A study of Homo sapiens with 10 samples.

How the data were processed

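Total RNA from A549 cells was labelled with Cy3 and hybridised to one-colour arrays, 5 for monolayer and 5 for RWV cultures, per the labels. Cells were grown in Dulbecco's medium with 10% foetal calf serum and 4 mM glutamine, RNA was extracted with a silica column kit, and labelling used an Agilent linear amplification kit, per the labels' protocols. The growth protocol in the labels mentions RWV for every sample, so the groups were taken from the sample titles. The values deposited by the authors are spot intensities on a linear scale, 45220 for each array. They are whole numbers from -66 to 65493, so that background appears to have been subtracted by the authors before deposit, and their medians differ between arrays, from 114 to 184.5, so that no normalization between arrays is visible in them. The scanner, the feature extraction software and the background method are not given in the sources used here. No flags for outlying or saturated spots were used, and array controls could not be told apart from other spots without annotation.

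Spots were named through the platform annotation, which listed 31425 spots, 31332 with 1 symbol and 93 with several. The 13795 other spots (30.5%) had no annotation used here, and spots with none or several symbols were left out of the gene tests. Symbols were updated by gene number against the RefSeq genes of assembly GRCh38.p14. This matched 31291 spots and left 41 unmatched, and 0 symbols changed. No coordinates are given, because the array annotation names no genome build.

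Intensities were quantile normalised over the 10 arrays with limma 3.58.1 in R 4.3.3, values below 0 were set to 0, a pseudocount of 50 was added and log2 was taken. Fold changes are on this log2(value + 50) scale, which understates the change of dim genes. The log2 values of all spots of a gene were averaged on each array, and 10575 of the 18334 genes had 1 spot. Of 1570 genes with at least 2 spots past the test by themselves, 79 had spots going in opposite directions. The groups were compared with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A gene counted as dim in a group when all its spots on all arrays of that group lay below a normalised intensity of 100, and as saturated when all its deposited intensities there were at or above 60000. A dim or saturated group gives only a bound. The fold is then given as at least the ratio of the bright group's mean to the higher of the dim level and the gene's own signal. No fold is given where that ratio is under 1, or for the 4654 genes dim in both groups or the 31 saturated in both. Tabular data were read with the R package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

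The 44 gene lists, 928 entries of which 861 were measured, were written from textbook knowledge before the data were examined, as were the tests, the alternatives and the rule for naming genes. Some genes belong to several lists. Lists were tested with limma camera at its preset correlation of 0.01, adjusted over the 44 lists, and beside it with an estimated correlation, by ranks, with fry and with an exact two-sided permutation test of the list mean over the 252 assignments of 5 and 5 arrays. By fry's mixed test, which asks for change in either direction, 43 lists passed. The named genes are the 10 largest rises and 10 largest falls among genes past the threshold whose RWV values all lay on the same side of all monolayer values, a panel of 20 marker genes, of which 17 were measured and 3 are not analysed here, and for each list up to 4 members past the threshold with the largest change or, where none passed, the member with the lowest p. This gave 180 genes. TYROBP, LAPTM5, PTPRC, COL1A1, COL1A2, COL3A1, PECAM1, VWF and CDH5 lie outside the rule and were chosen, after the results were seen, as abundant transcripts of other cell types.

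Some settings were fixed after the data were examined. The plan had values between arrays as deposited as its main setting and quantile normalization as the alternative, and these roles were exchanged because the intensities proved not to be normalised. The gene counts under 4 scalings, quantile normalization and none among them, had been seen when this exchange was recorded. The pseudocount, the dim level, the saturation level and the ceiling level of 65293 were set from the distribution of the values. The array sets were told apart by the lower end of the intensities, no slide or scan date being used here, and scaling to the 75th percentile, the fits with array sets, the removal of saturated spots, the fit without monolayer 4 and RWV 3, the exact list test and the test of gene families were added.

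The 5 arrays of a group are biological replicates per the labels, and no pair of arrays held the same values in more than 1.2% of spots. Correlations over genes were 0.939 to 0.989 within monolayer, 0.963 to 0.989 within RWV and 0.827 to 0.964 between groups. Equal replicate numbers in both groups were not taken as pairs, since nothing in the labels says they share a day or passage. Depth per array cannot be given for intensities. Between replicate spots of 1 gene on an array, over 235 genes with 10 or more spots, the median SD was 0.21 to 0.33 on the log2 scale. The procedure from normalization to gene calls was tested on simulated data for 5 against 5 arrays and 18334 genes. It recovered 77% of 100 genes changed 2-fold (log2 change 1) and 95% of 100 genes with a log2 change of 2. Of 181 calls 9 (4.97%) were false. Only these genes were changed, as many up as down and all of middle intensity. Simulated genes varied independently, and the ceiling was alike in both groups. The rates hold for such settings and may not carry over to the arrays here, where far more genes passed. Alternatives covered the normalization, a filter leaving out the 25% dimmest spots, the brightest spot per gene, a test per spot, a pseudocount of 200, array weights, trended and robust eBayes, a stricter threshold of 0.01, a replicate block and leaving out each array in turn.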

Results

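A549 is a human lung adenocarcinoma cell line, widely used as a model of alveolar type II epithelium. Its transcriptome was measured on 10 one-colour arrays, 5 from cells grown as conventional monolayers and 5 from cells grown in rotating wall vessels (RWV). An RWV is a slowly turning, fluid-filled culture chamber in which cells stay suspended under low shear and often form aggregates. The labels describe 5 biological replicates per culture condition and name RWV against monolayer growth as the comparison. Each array gave 45220 spot intensities, of which 31332 carried a single gene symbol and covered 18334 genes. The median spot intensity of the arrays was 122 to 184.5 in monolayer and 114 to 138 in RWV cultures, and the 75th percentile was 921 to 1685 and 875 to 1277. Arrays numbered 1 to 3 in both groups had 5th percentiles of 8 to 20, and those numbered 4 and 5 had 0 to 4, so these were treated as array sets 1 and 2. The number of arrays limits the precision of every value given here.

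The brightest spots were recorded differently in the 2 groups. Among spots at 60000 or above, the share that had reached 65293, within 200 units of the highest value, was 7.16% ± 1.08 (SD, n = 5) on monolayer arrays and 91.5% ± 1.39 (SD, n = 5) on RWV arrays, with ranges of 5.84% to 8.45% and 89.3% to 93.1%. This difference in readout went with the groups on every array, so its effect on dimmer spots cannot be fully separated from that of culture. For spots at 60000 or above, readout and culture condition cannot be told apart. Of the genes past the test, 155 had at least 1 such spot on at least 1 array, and among those named here they included CEACAM6, CHGB, TFF1, BIRC5, FN1, SLPI, MMP7, HERPUD1, FOS, KRT19, HMOX1, IGFBP3, HLA-C, ABCC3, BBC3, FADS2, HSP90AA1, TPI1, TPM1, BAMBI, GAA and GLA. All spots of the gene were at or above 60000 on 4 of 5 RWV arrays for GAA and VIM, on 3 for ABCC3, on 2 for FOS and KRT19 and on 1 for TFF1, HERPUD1, MMP7 and RPS19, and on 3 of 5 monolayer arrays for VIM, on 2 for GLA and RPS19 and on 1 for HMOX1, so that their values rest in part on a saturated signal. In the same way some values rest in part on arrays with a dim signal (below a normalised intensity of 100). These were 4 of 5 monolayer arrays for BPIFB1, C11orf96, CXCL8, GBP2 and IL6, 3 for TCN1, CLDN4, IL1B and ESAM, 2 for CFB, IFITM1, F5 and TNFSF10, and 1 for PIP, EGLN3, ALDOC, CLDN2, TPPP3, CP, SERPINA1, BMF, DEFB1 and H1-5. In RWV they were 4 of 5 arrays for MKI67, MCM10, RTKN2 and ESAM, 2 for GINS2, SPC25, DLGAP5, ANLN, ROPN1L, IL6 and LYZ, and 1 for CDC6, OIP5, NCAPG, ZWINT and KIF2C.

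**Figure D1:**
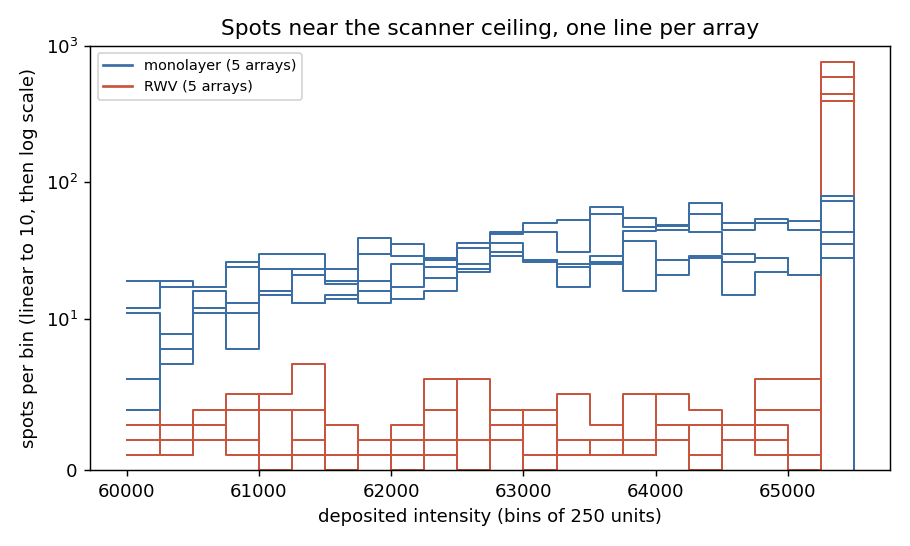
Spots per bin of 250 intensity units (vertical axis, linear to 10 and then logarithmic) against the deposited intensity from 60000 upward (horizontal axis, arbitrary intensity units), drawn as a line per array. In the 5 RWV arrays 393 to 757 spots lay at 65293 or above, and in the 5 monolayer arrays 27 to 71 did.

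RWV growth went with lower levels of cell cycle genes and higher levels of airway secretory, acute phase and immediate early genes by limma camera with its preset correlation (adjusted p = 0.33 with an estimated correlation for each of these lists). Of the 18334 genes, 2708 were higher and 2821 lower in RWV cultures at a Benjamini-Hochberg adjusted p below 0.05 (limma, 5 against 5 arrays), 5529 or 30.2% in all. A change of at least 2-fold was reached by 861 of the higher and 662 of the lower genes. In 4232 genes (23.1%, against 0.794% by chance) all RWV values lay on the same side of all monolayer values, and 4059 of these were past the test. Without normalization between arrays, 1037 genes were higher and 2518 lower, so that 29.2% of the calls were rises against 49% with it, with a median shift of -0.13 over all genes. Of the 180 genes named in what follows, 17 were then no longer past the test: ALDH3A1, BMF, CAPS, CDKN1A, CDKN1B, CYP1B1, EGFL7, EGR1, FOSB, H4C8, HSPA5, HSPH1, PARVA, PCK2, SESN2, STC2 and TNC. With array set as a block 5756 genes passed. Within array set 1 (3 against 3 arrays) 3056 genes passed, and within array set 2 (2 against 2) 1056 passed. Without monolayer 4 and RWV 3, the monolayer array farthest from and the RWV array nearest to the other group along the first principal component, 5585 genes passed. That component held 72.3% of the variance and placed the RWV arrays between 19.2 and 52.9 and the monolayer arrays between -69.8 and -21.1. In what follows, ± after a log2 fold change is the standard error of the limma fit and n is 5 arrays in each group.

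The largest rises included genes for secreted proteins. TCN1, which encodes the vitamin B12 binder haptocorrin, rose by 6.45 ± 0.37 on the log2 scale, from a normalised intensity of 55.9, dim on 3 of 5 monolayer arrays, to 9237 (limma adjusted p = 4.4e-06). PIP, the prolactin-induced protein of exocrine secretions, rose by 5.93 ± 0.57. CEACAM6, a cell surface adhesion glycoprotein, rose by 5.92 ± 0.66. The salivary-type cystatin CST1 was not above the dim level on any monolayer array and was at least 48.9-fold higher in RWV, and its relative CST2 was at least 36.5-fold higher. BPIFB1, an airway host defence protein, rose by 5.40 ± 0.35, the secretory granule protein CHGB by 5.24 ± 0.65, and complement factor B (CFB) by 5.13 ± 0.56. The trefoil peptide TFF1 rose by 5.09 ± 0.61 and C11orf96 by 4.87 ± 0.55. The limma adjusted p of these 10 genes was at most 0.00016. CST1 and CST2, like CEACAM6 and other CEACAM genes, are near-identical in sequence, so that their spots may share signal and their separate values are uncertain.

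The largest falls included genes of DNA replication and chromosome segregation. GINS2, a subunit of the replicative helicase complex, fell by 4.80 ± 0.64, from 8301 to 250.1 (limma adjusted p = 0.00023). CDC45, another part of that complex, fell by 4.55 ± 0.62, and the origin licensing factor CDC6 fell by 4.25 ± 0.55. BIRC5 (survivin) fell by 4.43 ± 0.82, and the mitotic kinase gene PBK fell by 4.38 ± 0.68. The log2 fold changes of the kinetochore and condensin genes SPC25, OIP5, NCAPG and ZWINT were -4.32 ± 0.57, -4.24 ± 0.54, -4.19 ± 0.64 and -4.15 ± 0.65. NPTX1, a neuronal pentraxin, was not above the dim level on any RWV array and was at least 15.3-fold lower there. The limma adjusted p of these 10 genes was at most 0.0017.

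**Figure D2:**
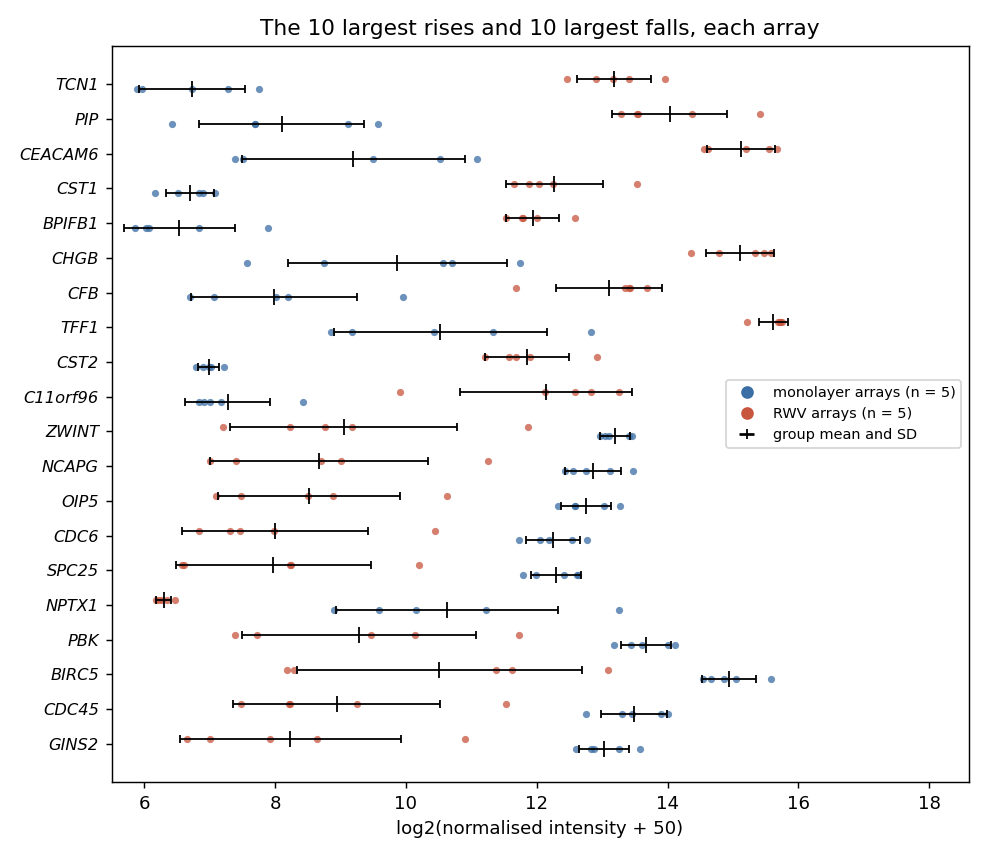
Log2 level (normalised intensity plus 50, horizontal axis) of the 10 genes with the largest rise and the 10 with the largest fall on each array, monolayer in blue and RWV in red (5 points each), with the group mean and SD in black. In each of the 20 genes the RWV points lie apart from the monolayer points, from TCN1 at 6.45 log2 units higher to GINS2 at -4.80.

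Cell cycle genes fell almost without exception. In the mitosis and G2/M list 30 of 30 measured members fell, and in the DNA replication and G1/S list 26 of 27 did, with 1 not past the test. Besides the genes above, the replication initiation factor MCM10 fell by 3.87 ± 0.42, the kinesin KIF2C fell by 4.15 ± 0.63 and the kinase PLK1 fell by 4.07 ± 0.57. The spindle protein DLGAP5 fell by 4.06 ± 0.63 and the proliferation marker MKI67 fell by 2.56 ± 0.32. The mean over the mitosis list was -3.32 ± 1.23 (SD, n = 5) in RWV relative to the monolayer mean, and that over the replication list was -2.74 ± 0.79 (SD, n = 5). RWV 3 stood apart, at -1.53 and -1.44, where the other RWV arrays lay between -4.54 and -2.99 and between -3.43 and -2.60. The limma camera test with its preset correlation gave an adjusted p of 1.5e-19 for each list, and the adjusted p = 0.33 with an estimated correlation. The exact permutation test over arrays gave p = 0.0079 for each, the smallest that 252 assignments allow. Adjusted over the list alone, 30 and 26 members fell. Within array sets 1 and 2 the mean was -3 and -3.79 for mitosis, and -2.59 and -2.96 for replication.

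Inhibitors of the cell cycle moved less and in mixed directions. In the list of p53 targets and cell cycle inhibitors, 5 of 21 rose and 2 fell (limma camera adjusted p = 0.22), and adjusted over the list alone the counts were also 5 and 2. GADD45A rose by 1.21 ± 0.23, SESN2 by 1.16 ± 0.31, CDKN1B (p27) by 0.91 ± 0.24, BBC3 (PUMA) by 0.72 ± 0.17 and CDKN1A (p21) by 0.64 ± 0.15. The rise of BBC3 rested on which of its 3 spots were used, with -0.03 from the brightest spot. Of the replication-dependent histones, 6 of 12 rose and 2 fell (camera adjusted p = 0.54), and adjusted over the list alone 6 rose and 4 fell. H1-2 rose by 1.40 ± 0.24, H4C8 by 0.91 ± 0.27 and H2BC21 by 0.86 ± 0.16, while H1-5 was at least 1.22-fold lower in RWV. H4C8 was not past the test without monolayer 1 or without RWV 1 (adjusted p 0.052 and 0.056).

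Airway secretory and mucin genes rose. Of 22 measured members 13 rose and none fell, also when adjusted over the list alone (13 and 0). BPIFB1 and TFF1 had the largest estimates of the list. The trefoil peptide TFF3 rose by 3.40 ± 0.39, and BPIFA1, which was dim in monolayer, was at least 9.42-fold higher in RWV. The gel-forming mucin MUC5AC rose 7.98-fold (log2 SE 0.17), from 234.3 to 2219. The list mean was 1.65 ± 0.21 (SD, n = 5) in RWV against a monolayer SD of 0.44, and RWV 3 had the lowest RWV value, 1.28 (limma camera adjusted p = 8.4e-06, and adjusted p = 0.33 with an estimated correlation). Within array sets 1 and 2 the mean was 1.42 and 2.01. In the type II pneumocyte and surfactant list 7 of 19 rose and none fell, again 7 and 0 adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.33 with an estimated correlation). The protease inhibitor SLPI rose by 3.29 ± 0.79, the lamellar body lipid transporter ABCA3 by 1.56 ± 0.13 and the membrane mucin MUC1 3.99-fold (log2 SE 0.32), and HHIP was at least 1.24-fold higher. SLPI and MUC1 are also members of the airway list, and the surfactant protein gene SFTPB was dim in both groups (44.2 in monolayer, 39.4 in RWV). The surfactant protein genes SFTPA1, SFTPA2 and SFTPC were not past the test (limma adjusted p 0.55, 0.32 and 0.42), nor was NKX2-1 (0.38). SFTPD was past it and at least 1.45-fold higher in RWV. Over the members of the type II list the mean was 0.45 and 0.61 within the array sets. Exact permutation p was 0.0079 for both lists.

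Other lung lineage lists showed no common direction. Of the type I pneumocyte genes, 3 of 15 rose and 2 fell (limma camera adjusted p = 0.78), with 3 and 3 adjusted over the list alone. The water channel AQP3 rose by 3.52 ± 0.81, AQP1 was at least 1.83-fold higher from a dim monolayer level, RTKN2 fell by 1.03 ± 0.15 and EMP2 fell by 0.96 ± 0.15. Of the ciliated cell genes, 4 of 14 rose and 2 fell (adjusted p = 0.38), with 5 and 2 adjusted over the list alone. The tubulin-binding TPPP3 rose by 4.11 ± 0.50, RSPH1 by 1.26 ± 0.21 and CAPS by 0.73 ± 0.13, and ROPN1L fell by 1.16 ± 0.21. Of the basal and squamous genes, 1 of 12 rose, KRT15 by 1.78 ± 0.44 (adjusted p of the list 0.76; 1 adjusted over the list alone). Of the keratins, 3 of 11 rose and 2 fell (adjusted p = 0.94; 3 and 3 adjusted over the list alone), with median and mean of opposite sign at 0.05 and -0.06. KRT19 rose by 1.55 ± 0.36, KRT7 fell by 1.71 ± 0.21 and KRT4 fell by 1.96 ± 0.59. KRT4 was not past the test without any of 6 arrays (monolayer 1, 2 or 3, RWV 1, 2 or 5; adjusted p 0.056 to 0.065).

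Complement, coagulation and acute phase genes rose. Of 30 measured members 19 rose and none fell, and adjusted over the list alone 22 rose. CFB was followed by ceruloplasmin (CP, 4.09 ± 0.93), the protease inhibitor SERPINA1 (3.90 ± 0.45) and coagulation factor F5 (3.74 ± 0.38). The mean of the list was 1.55 ± 0.38 (SD, n = 5) in RWV and varied between -0.81 and 0.67 in the monolayers, and RWV 3 lay at 0.88 where the other RWV arrays lay between 1.68 and 1.75. The limma camera adjusted p was 1.7e-08, and the adjusted p = 0.33 with an estimated correlation. The exact permutation p was 0.0079, and the mean within array sets 1 and 2 was 1.25 and 2.01.

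Antigen presentation genes were also higher. Of 21 measured members 9 rose and 1 fell, and 11 and 1 adjusted over the list alone (limma camera adjusted p = 1e-04, and adjusted p = 0.33 with an estimated correlation). HLA-DMB, a chaperone of class II peptide loading, rose by 2.10 ± 0.55, and the class I genes HLA-B, HLA-G and HLA-C rose by 1.94 ± 0.23, 1.70 ± 0.21 and 1.63 ± 0.17. Class I genes are close in sequence, so their separate values are uncertain. Members averaged 0.73 ± 0.19 (SD, n = 5; exact permutation p = 0.0079), and 0.68 and 0.79 within array sets 1 and 2. Of the interferon-stimulated genes 13 of 36 rose and 4 fell, and 14 and 5 adjusted over the list alone (camera adjusted p = 0.032, and adjusted p = 0.4 with an estimated correlation). IFITM1, IFITM3 and IFITM2, membrane proteins that restrict viral entry and are near-identical in part, rose by 3.81 ± 0.61, 2.30 ± 0.42 and 1.99 ± 0.43, and the GTPase GBP2 rose by 2.45 ± 0.41. This list was not past the test by ranks (adjusted p 0.053), without RWV 3 or RWV 5 (0.061 and 0.053), or within array set 1 (0.093), where its mean was 0.31 against 0.57 within set 2.

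Inflammatory and microbial recognition genes rose in part. Of the cytokines, chemokines and other NF-kB targets, 8 of 26 rose and 1 fell, and 10 and 1 adjusted over the list alone (limma camera adjusted p = 0.014, and adjusted p = 0.4 with an estimated correlation). The neutrophil chemokine CXCL8 rose by 3.82 ± 0.44, from 72 to 1668, prostaglandin synthase PTGS2 by 2.43 ± 0.58, CXCL2 by 2.39 ± 0.36 and IL1B by 2.36 ± 0.33. IL6 did not pass the test, at 0.18 ± 0.21 (adjusted p = 0.59). The list mean was 0.68 ± 0.15 (SD, n = 5), 0.82 within array set 1 and 0.46 within set 2, where the list was not past the test (adjusted p 0.29). Of the pattern recognition genes 7 of 20 rose and 1 fell, and 8 and 1 adjusted over the list alone (camera adjusted p = 0.0081, and adjusted p = 0.33 with an estimated correlation). The lipopolysaccharide co-receptor CD14 rose by 1.90 ± 0.38. The cathelicidin CAMP and lysozyme (LYZ), both dim in monolayer, were at least 1.77-fold and 1.01-fold higher, and the beta-defensin DEFB1 was at least 1.40-fold lower and dim in RWV. Over its members the mean was 0.39 ± 0.08 (SD, n = 5), and 0.36 and 0.45 within the array sets. Exact permutation p was 0.0079 for both lists.

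**Figure D3:**
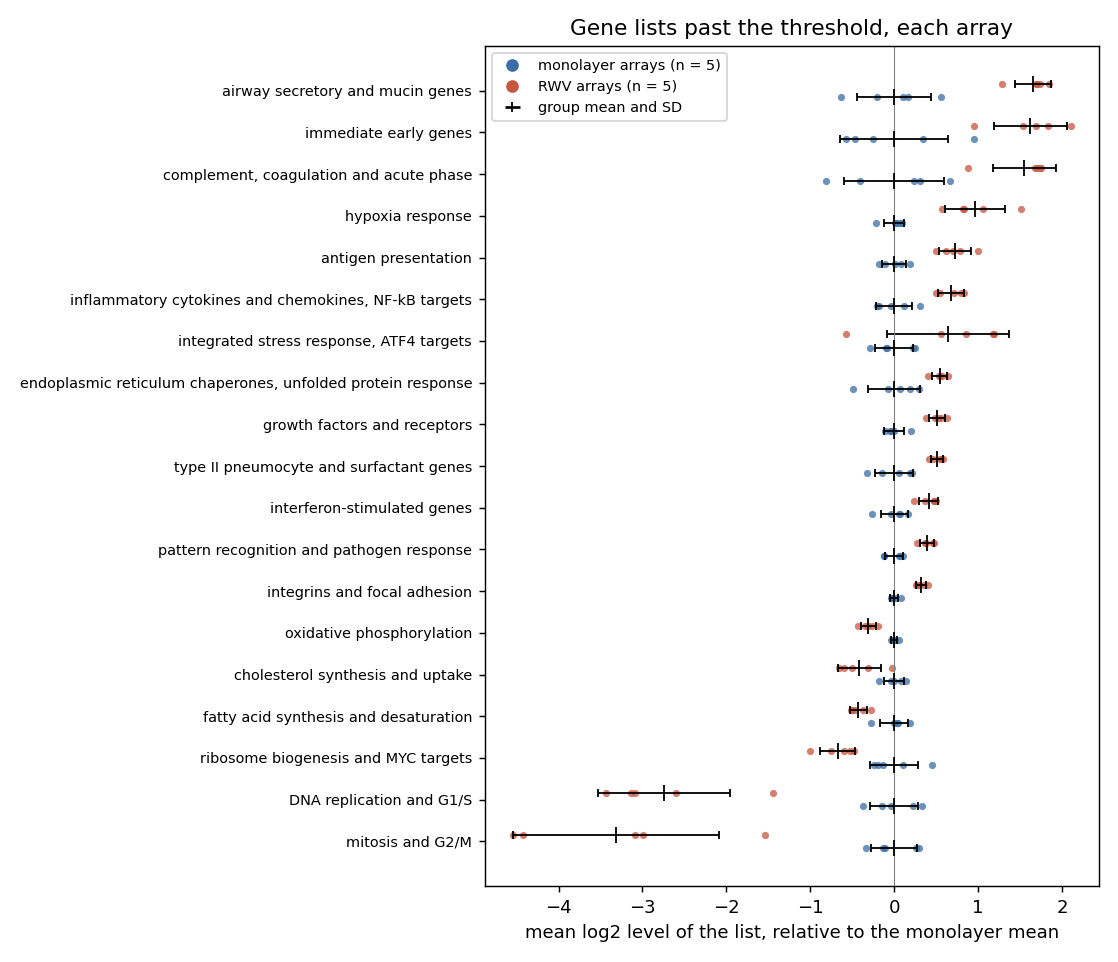
Mean log2 level of each of the 19 gene lists past the threshold on each array, relative to the monolayer mean (horizontal axis, log2 units), monolayer in blue and RWV in red (5 points each), with the group mean and SD in black. The RWV means run from -3.32 for mitosis to 1.65 for airway secretory genes, and RWV 3 lies nearest the monolayer arrays in the mitosis, replication and complement lists and below them in the ATF4 list.

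Hypoxia response genes rose. Of 27 measured members 19 rose and none fell, and 22 adjusted over the list alone. The oxygen-sensing hydroxylase EGLN3 rose by 3.04 ± 0.40, the collagen hydroxylase P4HA1 by 2.17 ± 0.19, STC2 by 1.79 ± 0.54, ANKRD37 by 1.64 ± 0.16 and the angiogenic factor VEGFA by 0.93 ± 0.16. The mean of the list was 0.96 ± 0.36 (SD, n = 5) against a monolayer SD of 0.12 (limma camera adjusted p = 2.7e-08, and adjusted p = 0.33 with an estimated correlation). The exact permutation p was 0.0079, and the mean was 1.01 and 0.89 within the array sets. Glycolysis genes split, with 3 of 16 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.93). Of the 16 members 8 had a spot at the saturation level, among them the 3 that fell, TPI1, ENO1 and PFKP. For these falls readout and culture condition cannot be told apart. The isozymes ALDOC, HK2 and ENO2 rose by 2.58 ± 0.50, 1.64 ± 0.27 and 1.57 ± 0.23, and triosephosphate isomerase TPI1 fell by 0.69 ± 0.16. HK2 averaged a normalised intensity of 62.3 over its 2 spots in monolayer, below the dim level, so its change is uncertain. STC2 was not past the test without any of 7 arrays (monolayer 2, 3 or 5, RWV 1, 2, 4 or 5; adjusted p 0.054 to 0.066).

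Immediate early genes rose, with 13 of 17 higher and none lower, and 14 adjusted over the list alone. FOSB rose by 3.09 ± 0.90, FOS by 2.88 ± 0.49, ATF3 by 2.81 ± 0.45 and JUN by 2.75 ± 0.45, all transcription factor genes induced within minutes of a stimulus. Members averaged 1.63 ± 0.43 (SD, n = 5) in RWV, and monolayer 5 at 0.95 met RWV 4 at 0.95 (limma camera adjusted p = 2.6e-07, and adjusted p = 0.33 with an estimated correlation). Exact permutation p was 0.016, and the mean within array sets 1 and 2 was 2.11 and 0.90. FOSB was not past the test without monolayer 2 or without RWV 2 (adjusted p 0.052 and 0.054).

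Stress response genes rose in part. Of the endoplasmic reticulum chaperones and unfolded protein response genes, 9 of 19 rose and none fell, again 9 and 0 adjusted over the list alone (limma camera adjusted p = 0.00058, and adjusted p = 0.41 with an estimated correlation). DNAJB9 rose by 1.97 ± 0.30, HERPUD1 by 1.29 ± 0.16, CRELD2 by 1.15 ± 0.17 and the luminal chaperone HSPA5 (BiP) by 0.82 ± 0.18. The list mean was 0.54 ± 0.09 (SD, n = 5; exact permutation p = 0.0079), and 0.40 and 0.75 within array sets 1 and 2. HSPA5 was not past the test from its brightest spot (adjusted p 0.16). Of the ATF4 targets of the integrated stress response, 7 of 18 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.026, and adjusted p = 0.63 with an estimated correlation). Besides ATF3 and STC2, the mitochondrial carboxykinase PCK2 rose by 1.40 ± 0.36, and the amino acid transporter SLC7A5 fell by 1.77 ± 0.28. The ATF4 list mean was -0.57 on RWV 3 and 0.55 to 1.19 on the other RWV arrays, and the exact permutation test gave p = 0.095. The list was not past the test within array set 1 (mean 0.43, adjusted p 0.22) or without monolayer 3, RWV 1 or RWV 5 (0.055 to 0.081).

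Of the heat shock genes 6 of 13 fell and none rose, also adjusted over the list alone, but the list was not past the test (limma camera adjusted p = 0.067). HSPA4L fell by 1.00 ± 0.13, HSP90AA1 fell by 0.72 ± 0.19, HSPH1 fell by 0.53 ± 0.18 and HSP90AB1 fell by 0.47 ± 0.13. HSPH1 was not past the test without any of 6 arrays (monolayer 1, 3, 4 or 5, RWV 2 or 4; adjusted p 0.064 to 0.11), HSP90AB1 was not without monolayer 1 (0.052), and HSP90AA1 was not with arrays scaled to the same 75th percentile (0.072). The list itself was past the test without monolayer 2 or without RWV 1 (adjusted p 0.046 and 0.036). Metallothioneins showed no member past the test among 8 (camera adjusted p = 0.93; 0 adjusted over the list alone), with the lowest p in MT2A at -0.50 ± 0.26 (adjusted p = 0.18). MT2A passed with array set as a block (adjusted p 0.027). In the NRF2 and glutathione list 2 of 20 rose and 5 fell (adjusted p = 0.25; 2 and 5 adjusted over the list alone). Heme oxygenase HMOX1 fell by 3.38 ± 0.44, from 45670 to 4332, and GCLC, the catalytic subunit of glutathione synthesis, fell by 0.78 ± 0.12. UGT1A6 rose by 1.24 ± 0.28 and the transporter ABCC3 by 1.04 ± 0.27. Of the xenobiotic metabolism genes 7 of 15 rose and 1 fell (adjusted p = 0.22; 7 and 2 adjusted over the list alone), led by TIPARP (1.81 ± 0.20), CYP2S1 (1.26 ± 0.35), CYP1B1 (1.08 ± 0.32) and ALDH3A1 (0.82 ± 0.26). CYP1B1 and ALDH3A1 lost their calls without any of 3 arrays (monolayer 3, RWV 1 or 2; 0.052 to 0.06) and of 5 arrays (monolayer 1, 4 or 5, RWV 3 or 4; 0.056 to 0.077).

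Genes of mitochondrial respiration, lipid synthesis and ribosome production fell. In the oxidative phosphorylation list 10 of 27 fell and none rose, also adjusted over the list alone (limma camera adjusted p = 0.00026, and adjusted p = 0.33 with an estimated correlation). CYC1 fell by 1.02 ± 0.12, NDUFA9 fell by 0.89 ± 0.11, NDUFB10 fell by 0.59 ± 0.12 and UQCRC1 fell by 0.57 ± 0.15. Over its members the mean was -0.31 ± 0.09 (SD, n = 5), and -0.34 and -0.26 within array sets 1 and 2. Of the cholesterol synthesis genes 7 of 18 fell and none rose, again 7 and 0 adjusted over the list alone (camera adjusted p = 0.013, and adjusted p = 0.55 with an estimated correlation). HMGCS1 fell by 1.49 ± 0.22, EBP fell by 1.25 ± 0.29, FDPS fell by 1.13 ± 0.19 and MVK fell by 1.05 ± 0.15. The mean of the list was -0.42 ± 0.26 (SD, n = 5), with RWV 3 at -0.02 and the array sets at -0.39 and -0.46. Of the fatty acid synthesis and desaturation genes 5 of 13 fell and none rose, and 6 adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.4 with an estimated correlation). The desaturase SCD fell by 1.19 ± 0.16, the desaturase FADS2 fell by 0.98 ± 0.24, fatty acid synthase FASN fell by 1.17 ± 0.23 and ACLY fell by 0.62 ± 0.17. Members averaged -0.43 ± 0.10 (SD, n = 5), and the list was not past the test within array set 2 (mean -0.37, adjusted p 0.075) or from the brightest spot per gene (0.079). The exact permutation p was 0.0079, 0.024 and 0.016 for the 3 lists.

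Of the ribosome biogenesis genes and MYC targets 18 of 24 fell and none rose, and 20 adjusted over the list alone (limma camera adjusted p = 1.8e-07, and adjusted p = 0.4 with an estimated correlation). BOP1 fell by 1.21 ± 0.30, NOP16 fell by 1.04 ± 0.17, the transferrin receptor gene TFRC fell by 1.01 ± 0.26 and NOLC1 fell by 1.00 ± 0.20. The list mean was -0.67 ± 0.21 (SD, n = 5; exact permutation p = 0.0079), and -0.61 and -0.77 within array sets 1 and 2. Of 29 cytosolic ribosomal protein genes 0 passed the limma test, under any of 4 scalings or adjusted over the list alone (camera adjusted p = 0.7). Their median was -0.02 with quantile normalization and 0.22 with arrays scaled to the same 75th percentile. The lowest p was that of RPS19, at -0.19 ± 0.09 (adjusted p = 0.13). Since 28 of the 29 had spots at the saturation level, a change in them would be hard to see. In the lysosome and autophagy list 9 of 24 rose and 3 fell (camera adjusted p = 0.087; 10 and 3 adjusted over the list alone). WIPI1, which marks forming autophagosomes, rose by 2.01 ± 0.39, the acid glucosidase GAA by 1.16 ± 0.19 (saturated on 4 of 5 RWV arrays) and cathepsin D (CTSD) by 0.99 ± 0.17, and the galactosidase GLA fell by 1.06 ± 0.21.

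The growth factor and receptor list and the list of integrins and focal adhesion genes were higher in part, the second in only some settings. In the growth factor list 14 of 33 rose and 2 fell, and 15 and 2 adjusted over the list alone (limma camera adjusted p = 0.0024, and adjusted p = 0.33 with an estimated correlation). The insulin-like growth factor binding proteins IGFBP1 and IGFBP3 rose by 3.41 ± 0.51 and 2.37 ± 0.25, EGR1 by 2.06 ± 0.62 and the ERK phosphatase DUSP6 by 1.73 ± 0.28. Over its members the mean was 0.51 ± 0.09 (SD, n = 5), 0.60 within array set 1 and 0.38 within set 2, where the list was not past the test (adjusted p 0.071). EGR1 was not past the test without monolayer 2, RWV 1 or RWV 2 (adjusted p 0.055 to 0.062). Of the integrin and focal adhesion genes 7 of 22 rose and 1 fell, and 7 and 2 adjusted over the list alone (camera adjusted p = 0.041, and adjusted p = 0.33 with an estimated correlation). The hemidesmosomal integrin ITGB4 rose by 2.84 ± 0.28, the laminin receptor subunits ITGA3 and ITGA6 by 1.13 ± 0.14 and 1.05 ± 0.13, and PARVA by 0.95 ± 0.16. The mean of the list was 0.32 ± 0.06 (SD, n = 5), and 0.33 and 0.32 within the array sets. The integrin call was lost without any of 6 arrays (monolayer 1, 3, 4 or 5, RWV 2 or 3; adjusted p 0.051 to 0.062), by ranks (0.067), within array set 2 (0.075) and without normalization between arrays (0.091). Exact permutation p was 0.0079 for both lists.

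Extracellular matrix and basement membrane genes moved both ways, with 8 of 24 higher and 3 lower (limma camera adjusted p = 0.45; 8 and 5 adjusted over the list alone). The type IV collagen COL4A2 fell by 3.07 ± 0.32, and fibronectin (FN1) and the laminin chains LAMB2 and LAMB3 rose by 2.72 ± 0.47, 1.84 ± 0.19 and 1.56 ± 0.40. Of the matrix proteases and inhibitors 5 of 21 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.22). Matrilysin (MMP7) rose by 3.42 ± 0.58, the urokinase receptor PLAUR by 2.25 ± 0.25 and the inhibitor TIMP1 by 2.02 ± 0.19, and the metalloprotease ADAM19 fell by 2.02 ± 0.20. Of the mesenchymal and EMT genes 2 of 22 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.76). Besides FN1, the tenascin TNC was past the test and higher in RWV but gives no fold, being dim in monolayer and at 68.26 in RWV, and the repressor SNAI1 fell by 1.71 ± 0.32 and FSTL1 fell by 1.62 ± 0.25. Vimentin (VIM, 0.05 ± 0.09, adjusted p = 0.75) and N-cadherin (CDH2, -0.45 ± 0.28, adjusted p = 0.28) did not pass the test. VIM had spots at the saturation level.

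Of the epithelial junction genes 6 of 23 rose and 3 fell, also adjusted over the list alone (limma camera adjusted p = 0.3). The claudins CLDN2, CLDN4 and CLDN3 rose by 2.12 ± 0.52, 1.20 ± 0.25 and 0.83 ± 0.19, and cingulin (CGN) was at least 1.49-fold lower and dim in RWV. E-cadherin (CDH1) was at 0.61 ± 0.37 (adjusted p = 0.25) and EPCAM at -0.85 ± 0.37 (adjusted p = 0.11), neither past the test, although EPCAM passed without monolayer 4 (-1.15, adjusted p 0.01). Of the YAP and TAZ targets 2 of 20 rose and 7 fell, and 2 and 8 adjusted over the list alone (camera adjusted p = 0.067). ANLN, which is also a cytokinesis protein, fell by 3.40 ± 0.52, AMOTL2 fell by 1.90 ± 0.32, DOCK5 fell by 1.29 ± 0.18 and CCN1 fell by 1.12 ± 0.27, while the ectonucleotidase NT5E rose by 1.99 ± 0.31. CCN2, another YAP target, was at 0.56 ± 0.25 and not past the test (adjusted p = 0.12), but passed without monolayer 5 (0.74, adjusted p 0.034). The YAP list was past the test without monolayer 2, monolayer 3 or RWV 1 (adjusted p 0.038 to 0.044) and within array set 2 (0.0075). Of the actin and SRF genes 2 of 25 rose and 7 fell, also adjusted over the list alone (adjusted p = 0.15), and within array set 2 the list was past the test (0.031). FHL2 and LIMA1 rose by 1.55 ± 0.17 and 1.21 ± 0.23, and the tropomyosin TPM4 fell by 0.85 ± 0.22 and TPM1 fell by 0.78 ± 0.21.

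Of the TGF-beta targets 2 of 17 rose and 3 fell, also adjusted over the list alone (limma camera adjusted p = 0.78), with a median of -0.07 and a mean of 0.01. The feedback inhibitor PMEPA1 fell by 1.59 ± 0.31 and ID3 fell by 1.31 ± 0.12, and JUNB rose by 1.34 ± 0.30. BAMBI, a decoy receptor, was saturated on every RWV array and at least 2.98-fold higher there. Of the Notch and Wnt genes 4 of 26 rose and 5 fell, and 5 and 7 adjusted over the list alone (adjusted p = 0.84), with a median of -0.16 and a mean of 0.06. The Wnt receptor ligase RNF43 rose by 2.84 ± 0.53, WNT7B fell by 1.35 ± 0.27, and the Notch ligands JAG2 and JAG1 fell, at -1.32 ± 0.25 and -1.31 ± 0.33. Of the apoptosis regulators 9 of 22 rose and 3 fell, and 10 and 6 adjusted over the list alone (adjusted p = 0.23). The death ligand gene TNFSF10 (TRAIL) rose by 2.42 ± 0.38, the inflammatory caspase CASP4 by 2.28 ± 0.36, and the BH3-only genes PMAIP1 and BMF by 1.26 ± 0.19 and 1.20 ± 0.36. BMF was not past the test without monolayer 1, RWV 1 or RWV 2 (adjusted p 0.051 to 0.064).

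Markers of other cell types gave few calls. Of the leukocyte list 3 of 14 rose, also adjusted over the list alone (limma camera adjusted p = 0.27), and these were CD14, LYZ and the lysosomal protein CD68 (1.71 ± 0.30). The abundant leukocyte transcripts TYROBP, LAPTM5 and PTPRC stood at normalised intensities of 103, 27.7 and 23.7 in RWV. Of the fibroblast list 1 of 13 fell, also adjusted over the list alone (adjusted p = 0.96), FBLN1 at -1.30 ± 0.15, with a median of 0.07 and a mean of -0.06. The fibroblast collagens COL1A1, COL1A2 and COL3A1 stood at 68.5, 20.8 and 28.6 in RWV. Of the endothelial list 1 of 13 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.96), EGFL7 by 0.66 ± 0.17 upward and ESAM at -0.67 ± 0.18. PECAM1, VWF and CDH5 stood at 48.6, 48.1 and 24.8 in RWV.

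In all, 19 of the 44 lists were past the threshold with the preset correlation of limma camera, 13 higher and 6 lower in RWV. With the correlation estimated from the arrays, 0 were past it and 4 had an unadjusted p below 0.05. By ranks 17 passed, and by fry, which tests each list by itself, 28 passed. The exact permutation test of list means, which also tests each list by itself, passed 27, among them 18 of the 19. With 30.2% of all genes past the limma test, a list can pass by itself without differing from other genes.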

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

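The tests of array brightness and of the ATF4 targets were chosen only after their results were seen, and those of mixed RNA, of saturated spots and of bins of intensity after the data and the gene counts had been examined but before their own results; the bins without normalization were added after all other results, and the limit of 10 calls per bin after theirs.

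Among 460 groups of 5 arrays, made up of array measures, list means and named genes in each culture condition, 30 held an array far from the other 4 by Dixon's ratio, where chance gives 23. RWV 3 accounted for 12 of them and monolayer 4 for 9, and genes that vary together do not count as independent. The list means of RWV 3 were 1.28 for airway secretory genes (other RWV arrays 1.69 to 1.85) and 0.88 for complement (1.68 to 1.75). On the log2 scale it was low in CFB (11.7), SERPINA1 (9.67), STC2 (7.79), IFITM1 (9.16), IFITM2 (12.7), IFITM3 (12.1), TFF1 (15.2), GAA (15.9) and CDKN1B (10.4), and high in the replication gene MCM10 (8.10). Monolayer 4 had list means of -0.21 for hypoxia, -0.48 for NRF2 targets, -0.36 for xenobiotic metabolism and 0.32 for actin genes, and stood apart in ADAM19 (10.7), FADS2 (11.3), H4C8 (8.999), HMOX1 (14.3) and MUC1 (7.73). RWV 4 was low in the immediate early genes FOS (15.0) and FOSB (10.1) and in CXCL2 (12.04). RWV 2 was low in ABCC3 (15.6), AMOTL2 (10.8) and BOP1 (11.2). RWV 5 was low in HMOX1 (10.4) and its 75th percentile of 1277 lay above the 875 to 986 of the other RWV arrays, and monolayer 5 was high in C11orf96 (8.42).

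RWV 3 and the monolayer arrays were spread along the axis that separates the groups. Monolayer 4 and monolayer 5 had similar 75th percentiles (1516 and 1685), and the mitosis list differed between them by 0.43 ± 0.062 (SE over 30 members). The complement list differed by -1 ± 0.27 (SE over 30 members). Each value rests on single arrays. The SD of the mitosis mean between monolayer arrays (0.27) includes both arrays, so a comparison with it cannot decide. A part of array brightness stays open. If RNA of a monolayer culture had been mixed into RWV 3, genes that fell and genes that rose should give the same share of it. The medians were 0.24 (quartiles 0.18 to 0.3, 223 genes) and 0.46 (0.12 to 0.71, 203 genes), a difference of -0.23 with overlapping quartiles, and the ATF4 list on RWV 3 lay -0.29 ± 0.31 (SE over 18 members) from the lowest other array, so that mixed RNA and a culture less far along in the change cannot be told apart. No biological explanation was tested, since the labels give nothing that sets RWV 3 apart.

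Bright spots piled up at the ceiling on RWV arrays and not on monolayer arrays, which could shift bright genes between the groups. Of the 5529 calls 5374 had no spot at the saturation level, which argues against saturation of their own spots as the cause of those calls. That 5449 genes passed without such spots adds nothing, since few calls had one. These spots were removed after quantile normalization, so an effect of the ceiling through that step was not tested. For the 155 calls with such a spot, readout and culture condition cannot be told apart, since the shares at the ceiling did not overlap between the groups. A readout setting that shifts spots by their brightness, as the whole cause, would send the calls at each level the same way. In 10 bins of mean intensity without normalization the rarer direction held 23.1% to 39.1% of the calls in 9 bins. It held 0% in a bin with 1 call. This argues against such a setting as the whole cause. The imbalance tended to be larger in brighter bins, with 39.1% in bin 5, counted from the dimmest, and 23.1% in bin 10. In bin 10, 129 calls were higher and 430 lower in RWV. The 40.9% or more found after quantile normalization adds nothing, since that step balances rises and falls. The trend over brightness leaves open that such a shift made a part of the calls.

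Spots without a gene in the annotation, not used in the comparison of genes, carried differences too. Of these 13795 spots, 1729 (12.5%) were past the limma threshold, 743 higher and 986 lower in RWV, and 488 of them by at least 2-fold.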

How the results depend on the processing

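The tests within array sets, with array set as a block, without saturated spots, with 75th percentile scaling and without monolayer 4 and RWV 3 were chosen after the data were seen. Against 5529 genes (2708 higher, 2821 lower) and 19 lists, omitting normalization between arrays gave 3555 genes (1037 higher; of 180 named genes 17 lost and 1 gained the call), and the cause was not tested. A stricter adjusted p of 0.01 gave 3503 (1666 higher, 1837 lower), and a test of each spot, which counts genes several times, 8957 (4333 and 4624). With fewer arrays, array set 1 gave 3056 (1432 and 1624) and set 2 gave 1056 (528 and 528). Estimating the correlation within lists left 0 lists. Leaving out each array in turn gave 4482 genes (without monolayer 1) to 5643 (without RWV 3), 2184 to 2808 higher, 2298 to 2835 lower, and 17 to 21 lists. Other settings gave 4744 to 6057 genes, apart from 4232 by the exact rank test, and 17 to 20 lists. BBC3 turned to -0.0269 from its brightest spot, and no other named call changed direction; its cause was not tested. With the replicate number as a block 5399 genes and 19 lists passed, and of the named genes ALDH3A1 was lost. Same-numbered arrays correlated at 0.034, 0.33, -0.22, 0.097 and 0.13 in their deviations. These few values show no common pairing by number and cannot exclude one. Signal over background limits the 4654 genes dim in both groups.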

Other observations

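All tests in this part except the counts of other splits were chosen after the results were seen.

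Some families of genes with a shared symbol stem moved together. Among 315 groups of at least 8 genes that share the stem of their symbol, 40 passed limma camera with its preset correlation and 0 with an estimated correlation. Of 50 MRPL genes, for proteins of the large mitochondrial ribosome subunit, 29 fell and 1 rose, and of 28 MRPS genes, for the small subunit, 20 fell (adjusted p = 2.8e-07 and 2.5e-06, and adjusted p = 0.46 with an estimated correlation for both). Nucleoporins followed, with 20 of 25 NUP genes lower and 1 higher (adjusted p = 2.8e-07), as did the proteasome lid and base genes, with 9 of 13 PSMD genes lower (adjusted p = 5e-04); the adjusted p = 0.46 and 0.5 with an estimated correlation.

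Among the families that were higher (adjusted p = 0.46 with an estimated correlation for each of the 4 named), 8 of 14 UGT genes for glucuronosyltransferases rose, led by UGT2B15 (adjusted p = 0.00026), and 8 of 18 KLF transcription factor genes rose, led by KLF2 (adjusted p = 0.002), with KLF2, KLF6 and KLF4 also in the immediate early list. Of 10 CEACAM genes 5 rose (adjusted p = 0.015), and of 10 HOXB genes 4 rose (adjusted p = 0.0084), led by HOXB5. Members of the UGT2B and CEACAM groups are close in sequence and their spots may share signal, so their separate values are uncertain. The medians of all 8 families kept their sign under 4 scalings between arrays, and without normalization 23 MRPL and 13 MRPS genes were lower and 5 KLF and 3 HOXB genes higher.

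Chance assignment of arrays was tested with 100 of the 126 splits into 5 and 5. For genes, 1 split gave a count as large, the real one with 5529, and the highest other gave 0. Such a count is thus not what an arbitrary split of these arrays gives. Every other split puts arrays of both culture conditions on each side, which widens the spread within the sides and lowers the count. The test cannot tell culture from a readout that went with the groups. For lists, 3 splits, the real one included, gave a count as large as the real 19, and the highest other gave 20. The other splits had a median of 10 lists past the threshold. With the preset correlation the count of lists therefore does not exclude chance for any single list.

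Secretory and acute phase genes rose in RWV, which fibroblasts, leukocytes or endothelial cells in these cultures could also bring. Of 9 abundant transcripts of such cells, each compared with itself between the groups, 0 were past the test and higher in RWV, but 8 lay below the dim level in at least 1 group. In the fixed lists the highest log2 fold change plus 2 SE was 0.475 among 13 fibroblast, 0.999 among 13 endothelial and 2.66 among 14 leukocyte genes, where the lower quartile of the risen secretory and acute phase genes was 1.40. Only 2, 1 and 5 of these members lay above the dim level in both groups, and CD14, CD68 and LYZ of the leukocyte list were higher, so fibroblasts, leukocytes or endothelial cells in the RWV cultures stay open. The choice among 4 scalings between arrays did not account for the rise. These scalings moved the median of all genes by up to 0.13, and the airway secretory and complement lists kept medians of at least 0.993. Both lists kept their calls (limma camera adjusted p at most 8.4e-06 with the preset correlation). With an estimated correlation the camera adjusted p was 0.33 for both under quantile normalization. The kept calls add little, since camera compares a list with the other genes and a shift common to all genes largely cancels.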
